A study of Mus musculus with 6 samples.

How the data were processed

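RNA of macrophages from mouse pancreatic tumours was sequenced in 6 libraries, 3 of Cxcr4+ and 3 of Cxcr4- cells. Total RNA was extracted with TRIzol, per the labels' protocols. Per the submitters' processing notes, cutadapt, HISAT2 and StringTie were used with the genome build GRCm39; their versions, the gene annotation release, the counting settings and whether strand was used are not given in the sources used here. The authors deposited 1 table of 53647 genes with estimated counts and FPKM for each library, per the file headers. Each of its 12 value columns named 1 sample, and the group of each sample was taken from the labels.

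The deposited counts are expected (estimated) counts that were already whole numbers, and rounding changed none of them. A count is not always 1 read: 43.2% of the values from 1 to 20 were multiples of 4, where 25% would be if they were spread evenly, and the ratio of count to FPKM was the same for a gene in every library up to 1 factor per library (largest SD of the log2 ratio 0.000897 over 8060 genes with over 500 counts in every library). The deposited FPKM values, scaled by the authors to gene length and library size, hold a constant minimum where the count was 0, which was read as 0. Low counts can overstate the number of fragments behind them, and the floor used for a group at 0 was 3 fragments, or 12 counts, per library. All library pairs differed by more than sampling noise (chi-square per degree of freedom 11.7 to 32.1, on counts divided by 4), so no library was counted as a sequencing copy of another. These values cannot tell libraries of separate mice from repeat libraries made of the same cells, which the labels leave open.

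The design was written before the data were examined, with 1 test for a table of FPKM and another for a table of counts. As the table held both, the count test was used, and limma-trend on log2(FPKM + 1), the design's test for FPKM, became an alternative once the table had been seen. Counts were fitted with edgeR 4.0.16 in R 4.3.3, by the quasi-likelihood test with its earlier dispersion method, after filterByExpr (minimum count 10, minimum total 15) and TMM scaling, with group as the sole term and the direction Cxcr4+ minus Cxcr4-. The filter kept 16031 genes and removed 0.0408 to 0.0581% of a library's counts. The standard error was the size of the log2 fold change divided by the square root of the F statistic, and p-values were adjusted by Benjamini-Hochberg. The biological coefficient of variation was 0.275.

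Gene lists for macrophage states, other cell types and RNA quality were fixed at the same time, 32 in all. The 27 with at least 5 tested members were tested by camera in limma 3.58.1 with a preset correlation of 0.01, beside camera with an estimated correlation and fry. GO and KEGG terms from the deposited table with 10 to 300 tested genes were tested in the same way. The naming rule, also fixed beforehand, took Cxcr4; up to 12 genes per direction with groups that did not overlap and a mean of at least 5 FPKM in the higher group, those past the threshold first and then those of smallest p, leaving out predicted genes, pseudogenes and receptor segments; up to 4 members per list; and the highest-mean gene past the threshold in each direction, which were Snora7a and Eif4h. Genes used to describe the identity of the libraries were chosen after their values were seen.

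The procedure was tested on simulated counts with the real means, library sizes and dispersions of the 16031 genes and 200 changed genes. It recovered 1.49% of genes changed 1.5-fold, 31.3% of those changed 2-fold and 69.7% of those changed 4-fold, with 6 false calls. With no change at all it made 1 call and called 0 lists, and a shift of 0.3 given to the proliferation list was recovered with an adjusted p of 1.55e-08. Simulated genes vary independently, which real genes do not.

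The alternatives tried were other pseudocounts, filters, scalings and weights, DESeq2 1.42.0, other thresholds, the replicate number as a block, leaving out each library, an estimated correlation, fry, and lists without shared genes. Counts divided by 4, edgeR's bias-adjusted method, library totals alone, limma-trend on log2(FPKM + 1), the libraries numbered 2 as a block, the libraries numbered 1 and 3 alone and, for the terms, leaving out each library were added after seeing the data. Transcript length and GC content came from GENCODE M21 transcripts, matched by gene identifier, and no coordinates of that release were used. Figures were drawn with matplotlib 3.10.9.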

Results

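The data were transcript levels in macrophages taken from pancreatic ductal adenocarcinomas grown in the pancreas of C57BL/6 mice and sorted by whether they carried Cxcr4, the receptor for the chemokine Cxcl12. There were 6 libraries of total RNA, 3 from Cxcr4+ and 3 from Cxcr4- macrophages. The libraries held 46444934 to 55740671 estimated counts each, the Cxcr4+ libraries each more than any Cxcr4- library, and 19457 to 20433 genes had a count above 0. The labels do not say whether the 3 libraries of a group came from separate mice, so the p-values measure the spread between these libraries. The libraries numbered 2 in both groups resembled each other more than the rest: the chi-square per degree of freedom was 16.5 between them, 20.4 to 32.1 between either and the other 4 libraries, and 11.7 to 17.8 among those 4. The design has a single comparison, Cxcr4+ minus Cxcr4-, which asks how the transcriptomes of the sorted populations differ.

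Both groups held abundant macrophage transcripts. Spp1, the secreted phosphoprotein osteopontin, had the highest FPKM of all genes, 27351 ± 2451 (SD, n = 6 libraries), and took 4.36 to 5.62% of the counts of a library. Lyz2, the macrophage lysozyme, stood at 6344 ± 865 FPKM, Cd68 at 1115 ± 83.2 and Csf1r, the receptor for macrophage colony-stimulating factor, at 79.5 ± 9.76. Ccl3, an inflammatory chemokine, had 2745 ± 601 FPKM, Tnf 154 ± 46.2 and Nos2, the inducible nitric oxide synthase, 63.2 ± 2.81. These genes were chosen after their values were seen, to describe the libraries, and not for a difference between the groups.

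Cxcr4 RNA was slightly higher in the cells sorted as Cxcr4+, at 9.27 ± 0.285 FPKM (SD, n = 3) against 7.42 ± 1.32 (n = 3), a ratio of means of 1.25. All 3 Cxcr4+ libraries lay above all 3 Cxcr4- libraries, with 9.04 as the lowest value of the first group and 8.56 as the highest of the second. The exact two-sided permutation test gave p = 0.1, the smallest that 3 against 3 libraries can give. In the edgeR quasi-likelihood fit the log2 fold change was 0.27 (SE 0.19, adjusted p = 0.999), so the difference did not pass that test. The log2 fold change was 0.11 without Cxcr4- replicate 2 and 0.44 without Cxcr4- replicate 1. Because the cells were sorted on Cxcr4, this value checks the labels and is not a finding of the comparison. As a check of the sort it is weak. The size of the log2 fold change lay at percentile 83.8 among tested genes with a mean of at least 1 FPKM. Groups also did not overlap for 10.4% of all tested genes. Only RNA was measured here, not the receptor protein. Cxcr4 lies on the reverse strand of chromosome 1 at 128515936 to 128520030 in GRCm39, the build of all coordinates here.

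Few single genes separated the sorted populations. Of 16031 genes tested, 2 were higher and 3 were lower in Cxcr4+ macrophages at an adjusted p under 0.05 in edgeR's quasi-likelihood test. Snora7a, a small nucleolar RNA encoded inside the ribosomal protein gene Rpl32, rose to 15.5 ± 1.59 FPKM in Cxcr4+ libraries (adjusted p = 0.0154 by edgeR, n = 3 per group). It had 113 to 149 counts there and 3 in each Cxcr4- library, less than 1 fragment of 4 counts, so its ratio of 39.7 has a wide exact 95% counting interval, 12.02 to 373, computed on 98 against 2 fragments. The histone gene H2ac18 had 264 to 478 counts in the Cxcr4+ libraries and 0 in each Cxcr4- library (adjusted p = 0.0315 by edgeR), which makes it at least 26.7-fold higher against a floor of 3 fragments, or 12 counts, per library. The floor and the interval cover counting error only.

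Nek7, a kinase that takes part in activating the NLRP3 inflammasome, fell from 7.34 ± 0.429 FPKM in Cxcr4- to 2.68 ± 0.223 in Cxcr4+ macrophages (log2 fold change -1.46, SE 0.11, adjusted p = 0.0169 by edgeR). Eif4h, a translation initiation factor, fell from 48.7 ± 6.49 to 23.5 ± 1.77 FPKM (log2 fold change -1.05, SE 0.10, adjusted p = 0.0315 by edgeR). Smyd4, a SET and MYND domain protein, fell from 17.0 ± 1.58 to 8.25 ± 0.841 FPKM (log2 fold change -1.05, SE 0.09, adjusted p = 0.0315 by edgeR). For each of these 3 genes the values of the groups did not overlap.

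**Figure D1:**
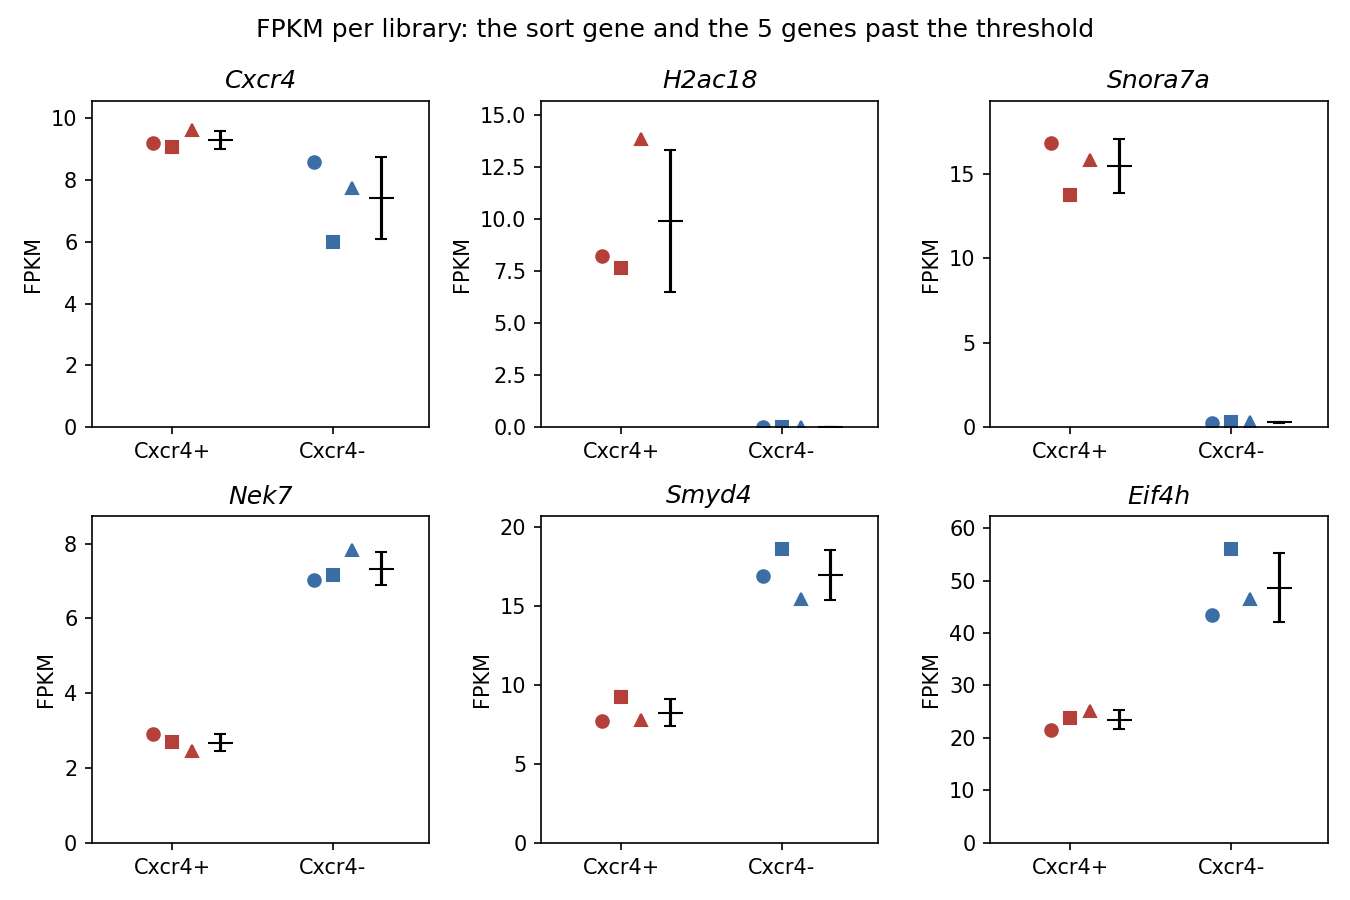
FPKM (vertical axes, each starting at 0) of the sort gene Cxcr4 and of the 5 genes past the threshold, per library, with circles, squares and triangles for replicates 1, 2 and 3, and black bars for the mean and SD of 3 libraries. Snora7a and H2ac18 lay near or at 0 in the Cxcr4- libraries, while Nek7, Smyd4 and Eif4h were lower in each Cxcr4+ library than in any Cxcr4- library.

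Snora7a (chromosome 6, 115784936 to 115785075, reverse strand) lies within Rpl32, and H2ac18 (chromosome 3, 96152813 to 96153398, forward strand) overlaps the predicted gene Gm20634 and has a near-identical copy, H2ac19, listed at 0 counts in every library. Nek7 lies on chromosome 1 at 138410613 to 138547879, Eif4h on chromosome 5 at 134648575 to 134668344 and Smyd4 on chromosome 11 at 75239259 to 75296531. The log2 fold changes of the 3 lower genes stayed close to their values when 1 library was left out, at -1.53 to -1.40 for Nek7, -1.10 to -1.02 for Smyd4 and -1.12 to -0.98 for Eif4h, but most calls were lost with fewer libraries. The fitted value for Snora7a rests on Cxcr4- counts under the floor and ran from 1.95, in limma-trend with a pseudocount of 5, to 5.37 over all alternatives. H2ac18 was not called with counts divided by 4 or with edgeR's bias-adjusted method, while the other 4 genes were. Without Cxcr4+ replicate 1, Cxcr4+ replicate 3 or Cxcr4- replicate 1, 0 of the 5 genes kept their call, and 4, 2 and 1 did without Cxcr4+ replicate 2, Cxcr4- replicate 2 and Cxcr4- replicate 3. With the libraries numbered 2 as a block, Snora7a, Nek7 and Smyd4 kept their calls, while H2ac18 (adjusted p = 0.0874) and Eif4h (log2 fold change -1.05, adjusted p = 0.0571) lost them. With the replicate number as a block 0 genes passed. In the 4 other libraries alone 0 of the 5 passed, with log2 fold changes of -1.48 for Nek7, -1.07 for Smyd4 and -0.96 for Eif4h. The adjusted p over all alternatives reached 0.226 for Smyd4, 0.195 for H2ac18, 0.159 for Eif4h, 0.0986 for Nek7 and 0.0972 for Snora7a. In all, 777 genes had an unadjusted p under 0.05 by edgeR, where 802 would be expected with no change and no structure among the libraries. There were 1485 with the libraries numbered 2 as a block and 1495 with the replicate number as a block. Other splits of the 6 libraries that parted those numbered 2, as the real split does, gave 292 to 335. Splits that kept them together gave 878 to 1737. Groups did not overlap for 10.4% of the tested genes, where chance gives 10% if the libraries are otherwise alike. DESeq2 passed 65 genes, which include all 5, Pfn1, Cd36, Sparc, Col6a1, Hp and mt-Atp8.

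The genes next in line did not pass the test, and their values follow the fixed naming rule. Among those higher in Cxcr4+ libraries, Pfn1, which encodes the actin-binding protein profilin, had 371 ± 46.2 against 161 ± 8.41 FPKM (log2 fold change 1.20, SE 0.13, adjusted p = 0.0722 by edgeR). Others were Ube2c (log2 fold change 0.54), a ubiquitin-conjugating enzyme of the anaphase-promoting complex, Pclaf (0.57), a partner of the replication clamp, Ncapg (0.53), a condensin subunit, Sass6 (0.46), a centriole protein, Dlgap5 (0.41), a spindle protein, Nek2 (0.59), a centrosomal kinase, Ptma (0.46), prothymosin alpha, and mt-Atp8 (0.63), a mitochondrially encoded subunit of ATP synthase. Their adjusted p ran from 0.350 for Ube2c to 0.757 for Nek2.

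Among genes lower in Cxcr4+ libraries that did not pass, Ptprn had 28.5 ± 1.34 against 47.8 ± 4.13 FPKM (log2 fold change -0.75, SE 0.09, adjusted p = 0.106 by edgeR). Fmnl2, a formin that elongates actin filaments, had a log2 fold change of -0.90 (adjusted p = 0.136). Hp, the haemoglobin-binding protein haptoglobin, had 11.6 ± 1.51 against 21.7 ± 2.65 FPKM (log2 fold change -0.90, adjusted p = 0.332). Pnpla2, the triglyceride lipase of lipid droplets, had a log2 fold change of -0.47 and Chst1, a keratan sulphate sulfotransferase, -0.42. The values for Rab15, Cept1, Ctla2b and Rom1 were -0.44, -0.78, -0.90 and -0.70.

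Genes of the cell cycle were higher as a set in Cxcr4+ macrophages. All 26 tested members of the proliferation list had a positive log2 fold change, with a median of 0.27 (camera adjusted p = 2.72e-11, adjusted p = 0.322 with an estimated correlation). No member passed on its own, with 0 of 26 past the threshold over all genes and 0 when adjusted over the list alone. Pcna, the replication clamp, had 110 ± 8.06 against 88.6 ± 6.92 FPKM (log2 fold change 0.30, SE 0.07) and Ccna2, cyclin A2, 13.3 ± 2.12 against 9.78 ± 1.39 (0.44, SE 0.13). The ribonucleotide reductase subunit Rrm1 had a log2 fold change of 0.28 and thymidine kinase Tk1 one of 0.27.

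Mitochondrially encoded transcripts, a list fixed as a sign of RNA quality, were also higher in Cxcr4+ libraries. All 15 had a positive log2 fold change, with a median of 0.20 (camera adjusted p = 1.34e-04, adjusted p = 0.280 with an estimated correlation), 0 passed over all genes and 1, mt-Atp8, passed when adjusted over the list alone. The mitochondrial share of counts was 5.42 to 5.77% in Cxcr4+ and 4.61 to 5.32% in Cxcr4- libraries. The ATP synthase subunit mt-Atp6 and the complex I subunit mt-Nd5 had log2 fold changes of 0.36 and 0.20. Nuclear genes of oxidative phosphorylation had a median of -0.04 (camera adjusted p = 0.341), and cytosolic ribosomal proteins, with 29 of 32 negative, a median of -0.06 (camera adjusted p = 0.0879).

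Complement and phagocytic receptors were higher as a set in Cxcr4+ macrophages, with 13 of 22 members positive and a median log2 fold change of 0.18 (camera adjusted p = 0.00825, adjusted p = 0.383 with an estimated correlation). Over all genes 0 members passed, and 2 passed when adjusted over the list alone. These were the scavenger receptors Msr1, at 32.1 ± 1.59 against 25.1 ± 0.442 FPKM (log2 fold change 0.35, SE 0.08), and Cd36, at 17.9 ± 4.13 against 9.43 ± 1.47 (0.92, SE 0.22). C1qb and C1qa had larger log2 fold changes, 3.75 and 2.49, but at most 84 and 29 counts in a library, close to the detection floor. The complement component C3 was among the 9 members that went the other way, with a log2 fold change of -0.40. Without Cxcr4+ replicate 1, the library with the most fibroblast transcripts, the median of the list was 0.06 and the call was lost (adjusted p = 0.0707). Over its alternatives the median ran from -0.04 to 0.34 and the adjusted p from 0.00132 to 0.682.

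The pan-macrophage list was also higher as a set, with 11 of 15 members positive and a median of 0.11 (camera adjusted p = 0.0152, adjusted p = 0.399 with an estimated correlation), while 0 members passed over all genes and 0 when adjusted over the list alone. Its members with the smallest p were C1qb (0.601 ± 0.545 against 0.0409 ± 0.0355 FPKM), the activating Fc receptor Fcgr1 (8.89 ± 1.84 against 6.18 ± 1.74) and C1qa (0.396 ± 0.0372 against 0.0671 ± 0.0683), so that the complement genes among them were close to the detection floor. C1qb, Fcgr1 and C1qa also belong to the complement and phagocytic receptor list, so they count in both sets. The pan-macrophage call was lost without Cxcr4+ replicate 1, the library with the most fibroblast transcripts (adjusted p = 0.229). It was also lost without Cxcr4- replicate 2 (adjusted p = 0.0604), within a range over all alternatives of 0.00248 to 0.399.

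The lists for the other macrophage states did not pass with group as the sole term. The monocyte list had 10 of 15 members negative and a median of -0.17 (camera adjusted p = 0.0516), with Hp as the 1 member past the threshold when adjusted over the list alone and the integrin subunit Itgal at -0.34. In lipid handling (adjusted p = 0.566) the lipid receptor Trem2 stood at 7.36 ± 0.556 against 5.16 ± 0.291 FPKM, lipoprotein lipase Lpl at 9.52 ± 0.759 against 7.13 ± 0.543 and apolipoprotein Apoe at 3.64 ± 0.206 against 4.55 ± 0.267. Matrix remodelling had a median of 0.22 (adjusted p = 0.0743), with the metalloproteinase Mmp19 at -0.30 and the protease Ctsl at 0.21. Hypoxia and glycolysis had a median of -0.06 (adjusted p = 0.10), with hexokinase Hk1 at -0.47 and glucose phosphate isomerase Gpi1 at -0.16.

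In the inflammatory cytokine list (median 0.15, camera adjusted p = 0.692) the gene with the smallest p was the inflammasome sensor Nlrp3, at 2.38 ± 0.510 against 3.78 ± 0.879 FPKM. Type I interferon response genes had a median of 0.14 (adjusted p = 0.10), with Ifit3, of smallest p, at 0.96, and immediate early genes a median of -0.13 (adjusted p = 0.10), with Fosl1, of smallest p, at -0.46. The immediate early list passed as lower with the libraries numbered 2 as a block (median -0.12, adjusted p = 0.0185) and with the replicate number as a block (-0.13, adjusted p = 0.00352). Its median was positive without Cxcr4+ replicate 2 (0.13) and without Cxcr4- replicate 1 (0.09). The list passed as lower without Cxcr4+ replicate 1, Cxcr4+ replicate 3 or Cxcr4- replicate 2 (-0.29, -0.16 and -0.34). Its adjusted p over all alternatives ran from 1.21e-06 to 0.838, the highest being that of camera with an estimated correlation. The adjusted p was 0.347 for tissue-resident macrophage genes, 0.498 for alternative activation, 0.442 for immune suppression and checkpoint genes, 0.313 for angiogenesis, 0.220 for chemokine receptors, 0.474 for Toll-like receptor and NF-kappaB signalling, 0.756 for class II and 0.739 for class I antigen presentation. The direction of camera's test differed in sign from the median for chemokine receptors (median 0.05, tested lower), class I antigen presentation (0.01, tested lower), alternative activation (-0.04, tested higher) and lipid handling (-0.0032, tested higher).

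Fibroblast, epithelial and neutrophil markers differed as sets between the groups by camera with the preset correlation. Exact permutation tests of the mean log2 level of each list, 3 against 3 libraries, gave p = 0.3, 0.2 and 0.1. The smallest p that design can give is 0.1. Fibroblast and core matrix genes were higher in Cxcr4+ libraries, with 16 of 17 tested members positive and a median log2 fold change of 1.53 (camera adjusted p = 9.29e-09, adjusted p = 0.399 with an estimated correlation), and 0 passed over all genes or when adjusted over the list alone. Most of this came from Cxcr4+ replicate 1: the summed FPKM of the list was 41.5 there, 7.85 and 10.8 in the other Cxcr4+ libraries, and 4.90 to 10.1 in the Cxcr4- libraries. Without that library the median was 0.20 (adjusted p = 0.0197, within a range over all alternatives of 5.27e-16 to 0.512). Sparc, a matrix glycoprotein, had 2.82 ± 2.08 against 0.697 ± 0.0935 FPKM, and the collagen genes Col6a1 and Col3a1 had 0.679 ± 0.538 against 0.132 ± 0.0625 and 0.682 ± 0.638 against 0.159 ± 0.0563.

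Tumour and ductal epithelial markers were lower as a set in Cxcr4+ libraries, with 11 of 12 negative and a median of -0.90 (camera adjusted p = 1.24e-05, adjusted p = 0.336 with an estimated correlation); 0 passed over all genes and 1, the lectin Lgals4, when adjusted over the list alone. Lgals4 had a log2 fold change of -1.02 (SE 0.23) and the adhesion molecule Epcam 0.268 ± 0.148 against 0.612 ± 0.155 FPKM. Of the 20 listed epithelial genes, 19 had a mean under 1 FPKM, and the highest, Lgals4, had 1.12. The median over the list was 0.114 FPKM, so most of it lay close to the detection floor. Neutrophil markers were lower as well, with 6 of 9 negative and a median of -0.28 (camera adjusted p = 0.0152, adjusted p = 0.383 with an estimated correlation), and 0 passed over all genes or when adjusted over the list alone. The siderophore-binding protein Lcn2 had 443 ± 98.1 against 738 ± 140 FPKM and Mmp9 18.3 ± 2.38 against 22.1 ± 3.04. Several other neutrophil markers were absent or nearly so: S100a9, Ngp and Camp had 0 counts in every library and Ly6g at most 18. S100a8 and Csf3r were expressed, at 6.02 against 7.12 and 1.31 against 1.21 FPKM. Of the 19 listed genes in the deposited data, 15 had a mean under 1 FPKM. Neutrophil content itself was not measured. Without Cxcr4+ replicate 2 the neutrophil call was lost (adjusted p = 0.0561, within a range over all alternatives of 0.00285 to 0.383).

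Dendritic cell, B and plasma cell and endothelial lists had adjusted p of 0.717, 0.772 and 0.162. The T and NK cell, mast cell, acinar, islet and erythroid lists had too few tested members for camera. Exact permutation tests of their mean log2 level, 3 against 3 libraries, gave p = 0.1, 0.1, 0.5, 0.9 and 0.4, where 0.1 is the smallest that design can give. The levels behind the first 2 values were close, at 0.103 in Cxcr4+ against 0.0926 in Cxcr4- for T and NK cells. For mast cells they were 0.299 against 0.274. Of the listed genes, 23 of 24 and 11 of 12 had a mean under 1 FPKM. By fry, which asks whether a list's genes move together 1 way, 0 lists had an adjusted p under 0.05 and the smallest was 0.131. In fry's mixed test, which asks whether a list's genes change in either direction, the complement and phagocytic receptor list (adjusted p = 0.00620) and the monocyte list (adjusted p = 0.0157) passed.

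**Figure D2:**
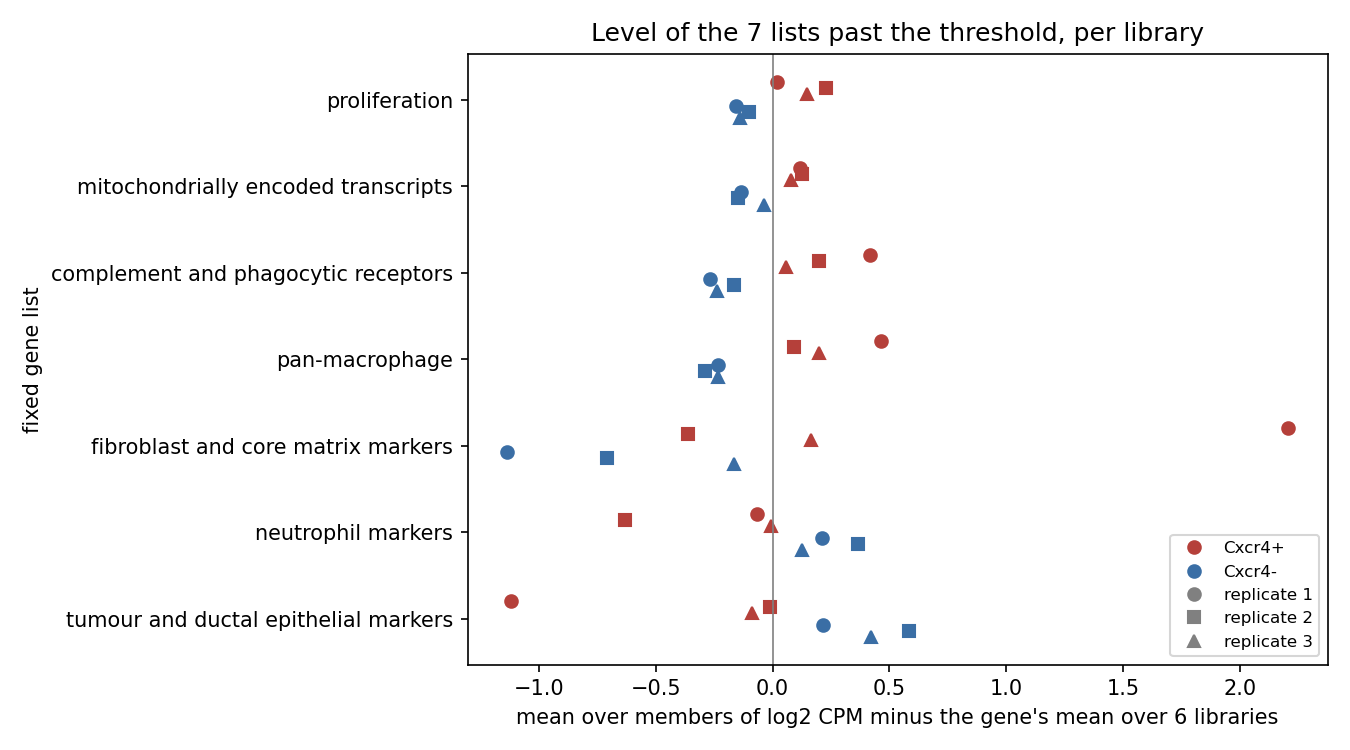
Mean over the members of each list of log2 CPM minus the gene's mean over 6 libraries (horizontal axis) for the 7 lists past the threshold (vertical axis), with red for Cxcr4+ and blue for Cxcr4- libraries and circles, squares and triangles for replicates 1, 2 and 3. Cxcr4+ replicate 1 stood at 2.21 for the fibroblast list, far from the other libraries, and the proliferation values lay from 0.02 to 0.23 in Cxcr4+ and from -0.16 to -0.10 in Cxcr4- libraries.

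Terms for DNA replication, the cell cycle and extracellular matrix were higher in Cxcr4+ macrophages with the preset correlation. Of 662 GO and KEGG terms tested, 11 were higher and 0 lower in Cxcr4+ macrophages by camera at an adjusted p under 0.05. With an estimated correlation 0 terms passed, and the adjusted p was 0.998 for each of the terms named. The smallest adjusted p with the preset correlation were those of DNA replication in KEGG (35 genes, median log2 fold change 0.16, adjusted p = 0.00132), cell cycle (116 genes, 0.08, adjusted p = 0.00280), DNA replication in GO (42 genes, 0.15, adjusted p = 0.00280), protein digestion and absorption (48 genes, 0.46, adjusted p = 0.00280) and homologous recombination (39 genes, 0.14, adjusted p = 0.00280). The terms past the threshold also held transmembrane receptor protein tyrosine kinase activity (median 0.60, adjusted p = 0.00755) and collagen-containing extracellular matrix (1.22, adjusted p = 0.0303). Without Cxcr4+ replicate 1, the library with the most fibroblast transcripts, protein digestion and absorption (median 0.18, adjusted p = 0.107), the collagen term (0.36, adjusted p = 0.503) and the kinase term (0.60, adjusted p = 0.153) lost their calls. Each of these terms also lost its call without Cxcr4- replicate 2 and without Cxcr4- replicate 3, and the kinase term without Cxcr4+ replicate 2. DNA replication in KEGG lost its call without Cxcr4+ replicate 2 (adjusted p = 0.228) or Cxcr4- replicate 3 (adjusted p = 0.124), and cell cycle without Cxcr4- replicate 2 (adjusted p = 0.0507). Homologous recombination lost its call without Cxcr4+ replicate 2 (median 0.07, camera adjusted p = 0.182) or Cxcr4- replicate 3 (0.08, adjusted p = 0.124). DNA replication in GO lost its call without Cxcr4+ replicate 2 (0.09, adjusted p = 0.216), Cxcr4- replicate 1 (adjusted p = 0.0779) or Cxcr4- replicate 3 (adjusted p = 0.0825). Of the 11 terms, 4, 3 and 9 kept their call without Cxcr4+ replicates 1, 2 and 3, and 6, 5 and 1 without Cxcr4- replicates 1, 2 and 3. The lowest terms, signaling receptor binding (adjusted p = 0.0679), visual perception, lipid catabolic process, lipid metabolic process and cell communication, did not pass.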

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

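Counts of called genes were small and moved with most settings, and the cause was not tested except where fewer libraries or genes were used. Against 2 genes higher and 3 lower, DESeq2 gave 28 and 37, which include all 5 genes. Genes higher numbered 4 with a pseudocount of 5 in limma-trend, 5 with array weights, 1 with a mean FPKM of at least 5, 1 with counts divided by 4 and 1 with the bias-adjusted method. Genes lower numbered 1 with limma-trend at pseudocounts of 0.1, 1 and 5, on FPKM rescaled to a common sum, with limma without trend, and with library totals alone. Leaving out 1 library gave 0 to 5 genes higher and 0 to 4 lower. The alternatives with divided counts, the bias-adjusted method, library totals, a pseudocount of 1 and the libraries numbered 2 were chosen after seeing the data.

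The replicate numbers did not pair the samples throughout. The same-number correlations of deviations were 0.04, 0.14 and 0.05 for numbers 1, 2 and 3. The highest with another number were 0.05, -0.055 and 0.02. Number 1 thus correlated better with another number, while number 2 correlated best with itself. With the libraries numbered 2 against the others as a block, 2 genes were higher and 2 lower, 3 of the 5 genes kept their call, and 1485 genes had an unadjusted p under 0.05. The 4 other libraries alone gave 2 higher and 3 lower with 0 genes shared, and 6 lists higher and 1 lower. With the replicate block, 0 genes were higher and 0 lower, with 1495 at an unadjusted p under 0.05. Either block gave 5 lists higher and 3 lower, the immediate early list being the one gained.

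Against 5 fixed lists higher and 2 lower, limma-trend gave 2 and 0 at pseudocounts of 0.1 and 1, 2 and 1 at 5, 3 and 1 on rescaled FPKM, 2 and 0 on quantile-normalized FPKM, 2 and 0 with array weights, and limma without trend 2 and 0. A mean FPKM of at least 5 gave 2 and 0, counts divided by 4 gave 3 higher, and lists without genes of another list gave 3 and 1. Leaving out 1 library gave 3 to 8 lists higher and 1 to 5 lower. With an estimated correlation, and by fry, 0 were higher and 0 lower, and the 11 annotated terms higher became 0. Leaving out 1 library, an alternative for terms added after seeing the data, gave 1 to 10 terms higher and 0 to 1 lower. The proliferation list was past the threshold in 23 of 25 alternatives, all but the estimated correlation and fry, with medians from 0.18 to 0.31, and so were the mitochondrially encoded transcripts, from 0.15 to 0.27. The fibroblast list was past it in 16 of 24, the epithelial list in 15 of 17 and the neutrophil list in 12 of 17. The limma alternatives kept genes with a mean of at least 1 FPKM. There, and with a mean FPKM of at least 5, the epithelial and neutrophil lists had fewer than 5 members left. They could therefore not be tested or called in those alternatives, nor the fibroblast list with a mean FPKM of at least 5. The complement and phagocytic receptor list passed in 12 of 25 and the pan-macrophage list in 11 of 25, so both lost their call in most. Of the lists that did not pass, immediate early and matrix remodelling passed in 5 of 25 alternatives each and type I interferon and ribosomal proteins in 3 each. Nek7 stayed past the threshold in 17 of 23 alternatives, Snora7a in 18 of 23, H2ac18 in 12 of 22, Smyd4 in 10 of 23 and Eif4h in 7 of 23, each with its direction kept. Pfn1 passed in 10 of 23. Cxcr4 did not pass in any of 23, with log2 fold changes from 0.11 to 0.44.

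At this depth and with 3 libraries per group, small changes were mostly out of reach of the test, since 1.49% of simulated 1.5-fold changes were recovered over the 16031 genes.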

Other observations

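The count of genes over other splits of the libraries, the leaving out of each library and the estimated correlation were planned before the data were examined. The splits of the lists, the matched random lists, the sums over overlapping genes, the genes on in 3 libraries, the marker list medians and the count of tissue-resident genes at 0 were tests chosen after the results were seen, and what each test would show was written down after seeing it.

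Several transcripts usual in tissue macrophages, and the monocyte genes Ccr2 and Ly6c2, were close to 0 in all 6 libraries, whichever way the cells were sorted. The genes named here were chosen after their values were seen. The mannose receptor Mrc1 had at most 35 counts in a library, arginase Arg1 at most 14, Ccr2 at most 54 and Ly6c2 at most 18, while Cd163 and Timd4 were listed at 0 counts throughout. C1qa, C1qb and C1qc had means of 0.232, 0.321 and 0.140 FPKM. Among class II genes, H2-Aa had 0.234 FPKM, H2-Ab1 168 to 265 counts and their activator Ciita at most 4 counts, beside 178 FPKM for the invariant chain Cd74. Ligand and alternative receptor of the axis were low too, with Cxcl12 at 0.0851 and Ackr3 at 0.0156 FPKM. The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty were expressed in every library, at 5.89, 12.4, 1.27 and 2.08 FPKM, and Xist had at most 38 counts.

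For these low tissue macrophage genes, RNA mostly from the other listed cell types is argued against by the marker lists. The highest median among those lists was 0.350 FPKM, for the fibroblast list, against 45.4 for the pan-macrophage list. Single markers were high all the same, with the neutrophil marker Lcn2 at 591 FPKM and the B cell marker Ighm at 34.1. The monocyte and tissue-resident macrophage lists also had low medians, 0.373 and 0.0283 FPKM. The medians therefore do not tell apart kinds of macrophage or monocyte. Cell types outside the fixed lists were not examined. Loss in the annotation or counting stays open, since 7 of the 22 tissue-resident members were at 0 in every library and 14 were under 1 FPKM, which neither shows nor excludes it. A source other than freshly sorted tissue macrophages, such as cultured cells, could not be tested with these labels. The design gives no group that bears on this pattern, so no biological explanation was tested.

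The higher level of the proliferation list in Cxcr4+ macrophages is not accounted for by gene length or GC content as matched here. Its median of 0.27 lay at percentile 100 of 10000 random lists matched on expression, length and GC, of which the highest was 0.11. Over the more highly expressed genes, however, the log2 fold change fell with GC content (Spearman correlation -0.27). The matching used 4 classes of GC content, and no other list was matched. Nor did the higher level of the proliferation list rest on a single library. Its median was 0.21 or more, and past the threshold, with any 1 library left out. Across the 10 splits of the libraries, 1, the real split, gave a median as large and the highest other was 0.18, but 10 splits are too few for a share under 0.05, and camera's unadjusted p was 4.92e-06, 1.24e-05 and 1.58e-05 in 3 of the other splits against 1.01e-12. Neither a biological difference between the sorted populations nor a difference in cell handling was tested, and both stay open. The list's call was lost with an estimated correlation (adjusted p = 0.322).

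The all-or-none difference at H2ac18 may come from estimates that switch between present and 0 in any libraries. The real split held 2 genes with at least 40 counts in 3 libraries and 0 in the other 3, H2ac18 and the overlapping Gm20634. The highest other split also held 2. Gene length was not part of this count. When H2ac18 was summed with H2ac19, Gm20634 and the antisense Gm20633, the log2 fold change was 4.19 (SE 0.87, adjusted p = 0.695 by edgeR) against a fitted 11.39 (SE 0.71) alone, which is no bound; the call ended because the fold fell and its error grew. The summed counts were still 354 to 629 in Cxcr4+ and 0 to 38 in Cxcr4- libraries, which argues against reads moved between these genes, while reads placed at other loci were not examined. The rule for reading this sum was changed after its value was known, from its adjusted p to its fold change against the standard error. The same sum decides nothing for Snora7a, which made up 0.0844% of the counts summed with Rpl32, nor for Nek7, which made up 99.8% of its sum, or Smyd4 and Eif4h, which overlapped no gene with a count. A biological difference between the sorted populations at these genes stays open and untested.

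The count of 5 genes called was reached by 2 of the 10 splits, the real one included, and the highest other split gave 5. For the fixed lists, 4 of the 10 splits called at least the 7 of the real split, and the highest other called 10. The other splits that parted the libraries numbered 2, as the real split does, called 2 to 5 lists. Those that kept these libraries together called 5 to 10. With 10 splits no share can be under 0.05. The splits point to a structure of the samples: the 4 other splits that kept the libraries numbered 2 together gave 878 to 1737 genes at an unadjusted p under 0.05, and the 5 that parted them 292 to 335, against 777 for the real split, which parts them into separate groups.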
